A study of Drosophila melanogaster with 3 samples.

How the data were processed

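ChIP-seq with an antibody against GFP was made on sonicated chromatin of whole Drosophila melanogaster pupae that carry a Snoo-eGFP fusion gene, with 3 biological replicates of 1 group per the labels. The replicate numbers 3, 5 and 6 were taken from the labels. The labels call the replicates biological, and how the animals were pooled for each is not given in the sources used here.

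The deposited files were peak lists in narrowPeak format on the dm6 and dm3 builds, for each replicate, for the pooled replicates and for the set of peaks that passed a threshold on the irreproducible discovery rate (IDR). The peak signal in these lists is the value the authors' peak caller gave, made against a control alignment, per the deposited file listings. The second value, the −log10 of the q-value of each peak, is also the authors', and it stood at its maximum in all 6633 peaks of the IDR list, so it was used only to break ties. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here, and the control alignment was not analysed here. Candidate lists held 30000 regions each, which includes regions of background by design, and the IDR list consisted of the 6633 regions with the highest signal in the pooled candidate list (22.1% of it). A signal was therefore compared only within 1 list, and total numbers of candidates were not compared between replicates. Because the number of reads is unknown, no interval that needs depth is given.

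Starts, exons, introns and gene names came from the Ensembl annotation of the BDGP6 assembly and sequence from the RefSeq assembly of the same build. Arm lengths in this reference were compared with the ends of the peaks on dm6, and no peak ran past an arm. Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used, and dm3 lists entered only as counts and in overlaps with each other. The annotation held 13968 protein-coding genes with a start on these arms.

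All statistics were computed with python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures with matplotlib 3.10.9. Summits were taken from the lists. A summit was near a start within 1000 bp, and 2 summits were the same within 150 bp. Shares near starts and in annotation classes (within 1000 bp of a start, exon, intron, intergenic, in this order) were compared with 1000 circular shifts of all summits along each arm. A difference of median signal was tested with 100000 permutations. Gene lists and arms were tested with Fisher's exact test against all other protein-coding genes, two-sided, with Benjamini-Hochberg adjustment over 18 lists or 7 arms and a threshold of 0.05. Motifs were counted on both strands in windows of 100 bp on each side of a summit and compared with windows 1000 bp up- and downstream, by an exact McNemar test against 1 flank drawn at random, adjusted over 20 motifs, with the fold taken over the mean of both flanks. Replicates were compared through the 6633 strongest regions of each, with 1000 shifts and a one-sided test. Exact 95% intervals are Clopper-Pearson intervals over genes, peaks or windows, and cover counting error only. Neighbouring genes and peaks are not independent, and none of these p-values measures the spread between animals.

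Designs, gene lists, motifs and alternatives were fixed before the data were examined, as was the rule for named genes. It took Snoo with every IDR peak in its body or within 1 kb, the first 25 protein-coding genes met going down the list, each the nearest with a start within 1 kb of a summit, which were reached after 40 peaks (peaks without such a start were passed over), the up to 4 bound members of each list with the highest signal, and the 5 strongest distal peaks. Of the list members, 5 matched no single protein-coding gene by symbol or synonym and were left out (Dl, d, Sarcalumenin, Trh and Mst57Dd). Through a synonym 11 were matched. Among these, ImpL3 and Slmb gave the same genes as the members Ldh and slmb. The member apoLpp was the same gene as apolpp. Each such gene was counted once in its list. Members shared between lists were kept in each. Later additions, with 16 more gene lists, a search for short sequences and counts of summits per gene, appear after the report and are marked there as chosen after the results were seen.

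Alternatives tried were the 3317 strongest IDR peaks, the 3681 peaks found in all 3 replicates, summits shared by the remaining pair when each replicate was left out (4347 to 4683 peaks), windows of 500, 2000 and 5000 bp, summits in the gene body, 10000 random lists matched on gene length and number of starts, lists without shared members, interval overlap in place of summit distance, smaller motif windows, shuffled windows of the same dinucleotide content, proximal and distal peaks alone, and the dm3 lists. Because summits in overlapping intervals are not independent, the strongest summit of each of 6220 groups of overlapping intervals was used as a further alternative, added after seeing the data.

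The procedures were tested on simulated data. Without a planted share near starts, 2 of 20 simulations of 6633 summits passed a p of 0.05, and with 30% planted 20 of 20 did. With 60% of the members of alternate lists bound among 13968 genes, 90.2% of the 450 lists were called, and 86.0% of those with fewer than 40 members. Of 300 lists left at 25%, 1.67% were called. A motif planted in 3% of 6633 windows was called in 10 of 10 simulations, and at random positions 0 of 200 motif tests passed. Random positions lack the difference in GC content between summits and flanks of the data (37.2 against 42.2%). The motif simulations therefore do not measure false calls that such a difference may give. Shares of 40 and 70% common summits were returned as 40.03 and 70.1%.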

Results

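Snoo is the fly member of the Ski and SnoN family, transcriptional coregulators that bind the Smad proteins of the TGF-beta and BMP pathways. Its position on chromatin was measured by ChIP-seq in whole Drosophila melanogaster pupae carrying a Snoo-eGFP fusion, which is made from an eGFP exon inserted in an intron of the gene. Sonicated chromatin was precipitated with an antibody against GFP. The series held 1 group of 3 biological replicates, numbered 3, 5 and 6, from pooled males and females of unknown age. No control library was among the samples, so the comparisons were between replicates and between regions of the genome. The authors gave 30000 candidate regions per replicate on the dm6 build and a list of 6633 peaks thresholded on reproducibility between replicates (irreproducible discovery rate, the IDR list). These peaks had a median width of 363 bp (109 to 1730 bp), and their signal ran from 128 to 4785 in the authors' units, with a median of 222. Read depth was not given in the sources used here and is treated as unknown.

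The tagged gene itself was among the occupied loci. Snoo spans 2L 7891187 to 7984196 on the minus strand of dm6 and held 15 IDR summits in its body or within 1 kb of it, 14 of them in introns. The strongest lay in an intron at 2L 7916192 to 7916720 with a signal of 942, and the next in an intron at 2L 7899966 to 7900308 with a signal of 877, and both were found in all 3 replicates. The remaining summit, 920 bp upstream of the gene start at 2L 7984988 to 7985182, had a signal of 242. Of the 15 summits, 10 were among the strongest 6633 regions of every replicate and 1 was among those of a single replicate. When all summits were moved together along their arms, Snoo held a mean of 4.47 summits. Over 1000 shifts, 15 or more occurred with p = 0.026 (one-sided permutation test). The test was chosen after the count was seen and not adjusted for the choice of gene. The shifts ran over whole arms, and any stretches where no peak could be called would lower this mean.

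**Figure D1:**
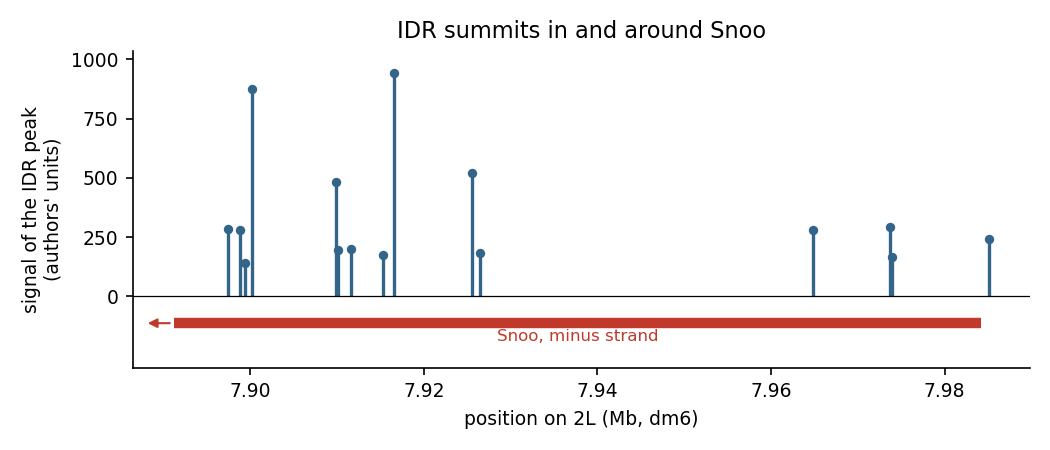
IDR summits in and around Snoo. The x axis gives the position on 2L in Mb (dm6), the y axis the signal of each IDR peak in the authors' units, and the bar the annotated gene on the minus strand. The 15 summits reach a signal of 942, and 14 of them lie in introns.

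The question of where the fusion protein sat relative to genes was addressed with the positions of all IDR summits. Of 6633 summits, 3571 lay within 1 kb of an annotated transcript start (53.8%, exact 95% interval 52.6 to 55.0%), against 23.6% ± 1.00 (SD over 1000 shifts) when the summits were shifted along their arms. The median distance to the nearest start was 782 bp, and 25.8% of the summits were within 150 bp of one. Exons away from starts held 1.30% of the summits against 15.1% for shifted summits, introns 31.5% against 36.1%, and intergenic sequence 13.3% against 25.2%. Each of the 4 classes differed from the shifted summits with an adjusted p of 0.002, the smallest that 1000 two-sided shifts can give (permutation test, Benjamini-Hochberg over 4 classes). The lower share in introns ended when the class of starts was narrowed to 500 bp, where introns held 38.4% of the summits (permutation test, adjusted p = 0.334). The 4 classes are exclusive and cover all summits, so the excess near starts lowers the other shares by construction. Of the summits away from starts, 2092 lay in introns, 884 in intergenic sequence and 86 in exons. Whether introns were favoured among these alone was not tested. The shifts ran over whole arms, and whether peaks could be called all along them was not examined. Shifted shares may therefore differ from those of the sequence where peaks could be called. The intervals treat peaks as independent and cover counting error only.

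**Figure D2:**
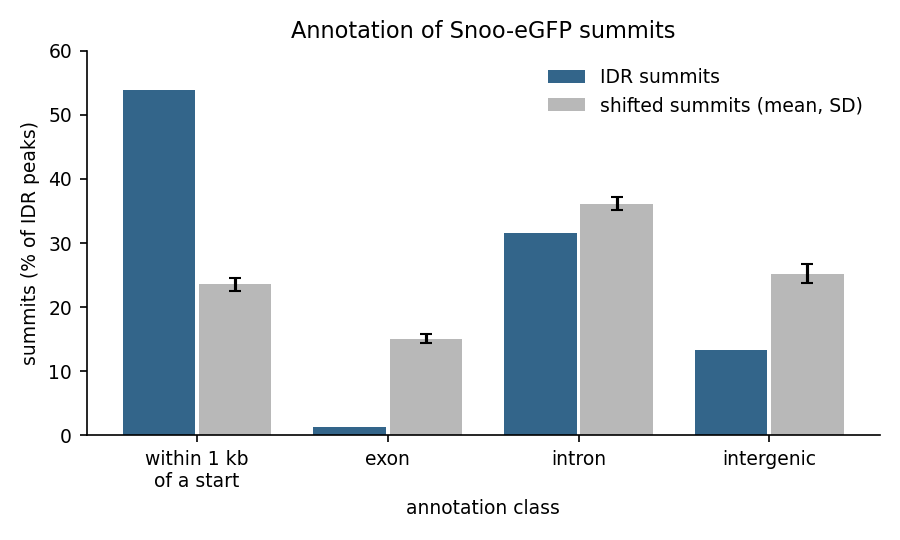
Annotation of the 6633 IDR summits on dm6. Bars give the share of summits in percent per class, blue for the IDR summits and grey for the mean of 1000 shifts with its SD. Summits within 1 kb of a start make up 53.8% against 23.6% for shifted summits, and exons hold 1.30% against 15.1%.

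Peaks near starts were slightly stronger than the others. The 3571 peaks within 1 kb of a start had a median signal of 225 (quartiles 165 to 390), and the 3062 distal peaks a median of 217 (quartiles 162 to 336). The difference of 8.40 passed a permutation test (p = 0.0237, 100000 resamples, two-sided), and among the 3317 strongest peaks it was 39.8 (p = 2e-05, the smallest these resamples can give). It ended with a window of 500 bp (4.48, permutation p = 0.277). Summits shared by 2 replicates carry the signal of 1 replicate, on a lower scale, so their differences are not comparable in size with that of the IDR list. There the medians near and away from starts were 76.8 and 75.4 without replicate 6 (permutation p = 0.423), 89.5 and 83.2 without replicate 3 (p = 0.0008) and 79.0 and 74.1 without replicate 5 (p = 0.00168). With the IDR list divided by signal into 4 equal parts, the share near starts was 59.0% in the strongest part and 51.6, 52.5 and 52.3% in the following ones.

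The strongest peak of the list lay at X 2703662 to 2704110 with a signal of 4785, its summit 39 bp upstream of Ugalt, which encodes a UDP-galactose transporter. The same summit lay 680 bp from a start of eIF2Bbeta, a subunit of a translation initiation factor. Next among the peaks within 1 kb of a protein-coding start came CG14100 (3L 19590408 to 19590850, signal 4249, 90 bp upstream of the start) and PNPase, a mitochondrial RNA-degrading enzyme, with a signal of 3325 in its 5' UTR at 3R 31404453 to 31404877. Lk6, a kinase of the cap-binding factor eIF4E, had a signal of 2932 in an intron at 3R 11760789 to 11761456, and mRpL41, a protein of the mitochondrial ribosome, 2905 upstream at 2R 15217533 to 15218003. Chro, which encodes the chromodomain protein Chromator, had 2768 in its 5' UTR, the gene of the RNA-binding protein Larp 2698 in an intron, and the small heat shock gene Hsp27 2687 at 138 bp upstream. The other genes among the 25 taken from such peaks were CG18549, CG1888, CenG1A, Tcs5, CG9147, CG31145, CG13921, Fkbp14, Art3, CG13390, CG4496, CG9663, CG3552, LPCAT, CG11309, HmgZ and gish, with signals between 1979 for gish and 2894 for CG18549. Each of the 25 peaks was among the strongest 6633 regions of all 3 replicates.

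Away from starts, the strongest peak lay in an intron of CG11050 (2L 6612386 to 6613003, signal 3561, 1027 bp from the nearest start). It was followed by an intron of ush, which encodes a Friend-of-GATA cofactor, at 2L 480554 to 481424 with a signal of 3439 and 4840 bp from a start. The other 3 of the 5 strongest distal peaks lay in an intron of CG32772 (X 4909953 to 4910770, signal 2962), 11978 bp from the start of CG13323 (2R 13034994 to 13035608, signal 2688) and 3755 bp from the start of CG31668 (2L 2202036 to 2202883, signal 2577). All 5 were found in the 3 replicates.

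A gene was called bound where an IDR summit lay within 1 kb of any of its starts, which held for 3526 of 13968 protein-coding genes (25.2%). Among 18 gene lists, genes of cytoplasmic ribosomal proteins stood apart most, with 76 of 85 bound (89.4%, exact interval 80.8 to 95.04%) against 24.9% of the other genes (odds ratio 25.5, adjusted p = 1.17e-34, Fisher's exact test, two-sided, Benjamini-Hochberg over 18 lists). The share was 80.0% without replicate 3, 71.8% without replicate 5 and 75.3% without replicate 6, with odds ratios of 16.7, 11.8 and 13.2. The strongest were RpS27 (3R 25247322 to 25247757, signal 1280.0, 1 bp from the start), RpS4 (signal 923, 5' UTR), RpS19b (signal 886, 900 bp upstream) and RpL7 (signal 876, 5' UTR). The median distance from start to summit was 22 bp in the 76 bound genes against 178 bp in 3450 other bound genes (permutation test, p = 0.0002, the smallest that 10000 resamples can give, a comparison chosen after the list result was seen). The authors' signal was made against a control alignment, which was not analysed here. Whether signal that any precipitation would give at these starts remains in these counts is therefore unknown.

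Genes of the response to ecdysone, the steroid hormone of metamorphosis, were bound in 18 of 27 cases (66.7%, odds ratio 5.95, adjusted exact p = 3.08e-05). The strongest were the ABC transporter gene E23 (2L 3354823 to 3355360, signal 1441, 213 bp upstream), the lactate dehydrogenase gene Ldh (signal 1139, 164 bp upstream), and the nuclear receptor genes Eip75B (signal 938, 5' UTR) and Hr3 (signal 881, 514 bp upstream). Against random lists matched on gene length and number of starts the odds ratio was 2.58 (permutation test, adjusted p = 0.0264).

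Components of several signalling pathways were bound more often than other genes. The members Dl of the Notch list and d of the Hippo list could not be matched and are not counted. For the Hippo pathway, which restrains growth, 12 of 17 genes were bound (70.6%, odds ratio 7.13, adjusted exact p = 0.000394), led by the cadherin gene ds (2L 715367 to 715765, signal 1176, upstream), app (signal 800), Mer (signal 573) and mats (signal 558). For EGFR and Ras signalling, 14 of 23 were bound (60.9%, odds ratio 4.62, adjusted exact p = 0.000936), with the kinase gene Raf (signal 804), the ligand gene spi (signal 788), edl (signal 588) and the gene of the secreted inhibitor aos (signal 422) as the strongest. For Notch signalling, 14 of 24 were bound (58.3%, odds ratio 4.16, adjusted exact p = 0.00148), among them the pathway inhibitor numb (2L 9449327 to 9449834, signal 1051, intron), the corepressor gene gro (signal 863), fng (signal 828) and E(spl)m3-HLH (signal 799). Against the matched lists the odds ratio was 4.52 for Hippo, 3.88 for Notch and 2.87 for EGFR and Ras signalling, with adjusted permutation p of 0.009, 0.0036 and 0.0264. For EGFR and Ras signalling the odds ratio was 2.62 without replicate 3 (adjusted exact p = 0.0594) and 8.00 without replicate 6 (7.19e-06), for Notch signalling 2.72 without replicate 5 (0.0628) and for Hippo 4.59 without replicate 3 (0.0083).

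The pathway in which Snoo family proteins act, TGF-beta and BMP signalling, had 14 of 29 components bound (48.3%, exact interval 29.4 to 67.5%, odds ratio 2.77, adjusted p = 0.0152). The strongest were magu (2R 10055514 to 10056877, signal 824, intron), shn, whose zinc finger protein acts with Mad and Medea (2R 11173364 to 11173880, signal 661, intron), the gene of the repressor of Dpp targets brk (X 7306581 to 7307904, signal 591, 815 bp upstream) and the receptor gene wit (signal 397, intron). This call ended against matched lists (odds ratio 1.91, adjusted permutation p = 0.139), among the 3317 strongest peaks (1.22, adjusted p = 0.723), among peaks found in all 3 replicates (2.35, adjusted p = 0.0902) and without the members shared with other lists (1.78, adjusted p = 0.228). It stood in the other 7 of 11 alternatives. Among them were those without replicate 3 (2.50, adjusted exact p = 0.0447), without replicate 5 (2.78, 0.0319), without replicate 6 (3.00, 0.0135) and with gene bodies (3.57, 0.00181). Target genes of Dpp, a BMP ligand, did not pass at starts, with 10 of 24 bound (41.7%, odds ratio 2.12, adjusted exact p = 0.132), brk, aos (signal 422), salr (signal 282) and peb (signal 236) being the strongest. At starts the odds ratio of the Dpp targets was 1.22 against matched lists (adjusted permutation p = 0.816). It was 1.18 without shared members (adjusted exact p = 0.877) and 1.17 among the 3317 strongest peaks (0.816). With summits anywhere in the gene body counted, it was 3.64 (adjusted exact p = 0.00508). Wnt genes (4.99, 0.0005) and sensory organ and proneural genes (2.62, 0.0489) gained a call as well. The count over gene bodies was not matched on gene length, and a longer body has more room for a summit.

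Cell death and autophagy genes were bound in 14 of 27 cases (51.9%, odds ratio 3.20, adjusted exact p = 0.00612), the strongest being the pro-apoptotic gene hid (3L 18185746 to 18186168, signal 827, upstream), Atg2 (signal 697), Atg17 (signal 615) and the apoptosis inhibitor gene Diap1 (signal 426). The call ended without replicate 3 (1.43, adjusted exact p = 0.523), without replicate 5 (1.91, 0.182), among peaks found in all 3 replicates (1.82, 0.268) and among the 3317 strongest (2.47, 0.0965), and it stood against matched lists (3.02, adjusted permutation p = 0.0171). Wnt signalling (10 of 23 bound, adjusted exact p = 0.0811), Hedgehog signalling (5 of 15, 0.583), sensory organ and proneural genes (8 of 22, 0.271) and homeodomain factors (11 of 50, 0.744) did not pass. Their strongest members were sgg (signal 1318), nkd (458), wls (402) and fz3 (268) for Wnt, rdx (919), dlp (306), slmb (235) and ptc (183) for Hedgehog, numb, neur (485), emc (301) and hry (258) for the sensory list, and tin (834), ct (299), cad (298) and so (277) for the homeodomain list. The Wnt list passed without replicate 6 (adjusted exact p = 0.00427) and with a window of 5000 bp (0.00628).

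Chemosensory receptor, cuticle, male germline and neuronal genes were bound less often than other genes. The receptors, of the Or, Gr and Ir families, were bound in 4 of 179 cases (2.23%, odds ratio 0.0666, adjusted exact p = 1.5e-16), with Ir94h (signal 500) and Gr32a (325) above Or9a (153) and Gr63a (150). Cuticle protein genes were bound in 4 of 122 cases (3.28%, odds ratio 0.0994, adjusted exact p = 4.27e-10), namely Cpr72Eb (signal 442), Cpr62Ba (247), Cpr73D (129) and TwdlT (128). Of the male germline genes, can alone was bound among 30 (signal 219, odds ratio 0.102, adjusted exact p = 0.00606). Of 40 neuronal genes 3 were bound (7.50%, odds ratio 0.239, adjusted exact p = 0.0153), the RNA-binding protein genes elav (X 523286 to 523695, signal 1152) and Rbp9 (828) and the syntaxin gene Syx1A (215). The neuronal call ended without replicate 3 (adjusted exact p = 0.243), without replicate 5 (0.149) and without replicate 6 (0.0884), among the 3317 strongest peaks (0.203), among peaks found in all 3 replicates (0.268) and with gene bodies (0.0785), with odds ratios of 0.308 to 0.461. Against matched lists it stood (0.109, adjusted permutation p = 0.0009). That of the germline ended without replicate 5 (adjusted exact p = 0.063), without replicate 6 (0.0528) and among peaks found in all 3 replicates (0.138), with odds ratios of 0.146 to 0.179, and it stood against matched lists (0.132, adjusted permutation p = 0.0264).

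Muscle structure genes (5 of 29, adjusted exact p = 0.446) and hemocyte and fat body genes (3 of 27, adjusted p = 0.153) did not pass against all other genes. Their strongest members were Msp300 (signal 1030), Zasp52 (559), Tm1 (351) and Mef2 (246) for muscle, and PPO3 (273), Tep4 (224) and apolpp (147) for the other list. Against random lists matched on gene length and number of starts both were bound less often, with odds ratios of 0.279 (permutation test, adjusted p = 0.0139) and 0.262 (adjusted p = 0.0264).

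**Figure D3:**
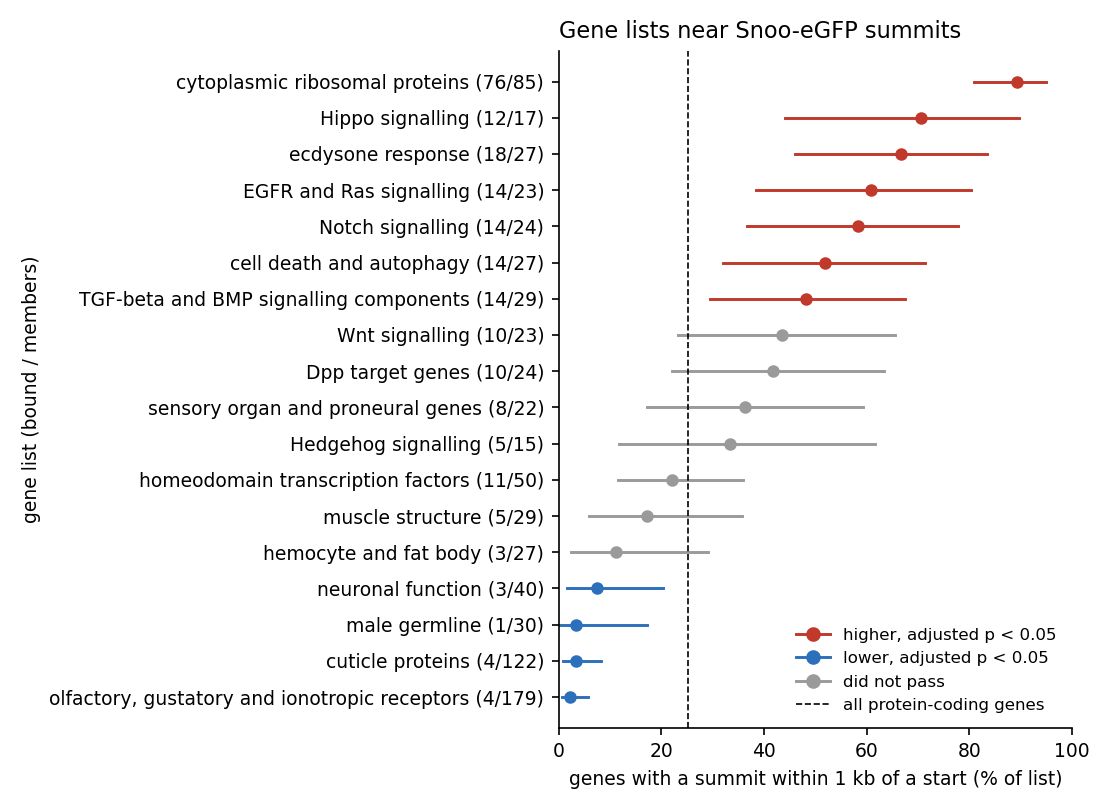
Share of genes with an IDR summit within 1 kb of a start in 18 gene lists, with exact 95% intervals over genes. The dashed line marks all protein-coding genes at 25.2%, red and blue lists passed the test as higher or lower, and grey lists did not pass. Cytoplasmic ribosomal protein genes lie at 89.4% and chemosensory receptors at 2.23%.

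Between chromosome arms, the share of bound genes ran from 23.6% on 2L to 26.4% on 3R among the large autosomal arms, with 24.2% on the X (532 of 2196) and 26.3% on chromosome 4 (21 of 80). None of these arms passed against the others (Fisher's exact test over 7 arms, adjusted p from 0.108 on 2L to 0.798 on chromosome 4). The Y had 0 of 23 genes bound, but none of the candidate lists held a region there, so no gene of the Y could be called bound and its test says nothing. Among the 3317 strongest peaks, chromosome 4 fell to 3 of 80 genes (3.75%) against 14.6% elsewhere (adjusted exact p = 0.0253). With summits shared by replicates 3 and 6, thus without replicate 5, the X had 16.2% against 18.4% elsewhere chromosome 4 7.50% against 18.1%, and 3L, which was higher, 19.8% against 17.7%, each with an adjusted exact p of 0.0251. Without replicate 6 the X had 16.9% against 19.5% (adjusted exact p = 0.0315), and without replicate 3 it had 19.9% against 19.7% (adjusted p = 0.889). Replicate 3 held 14.6% of its strongest regions on the X, against 18.4% in the other replicates.

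Sequence at the summits was compared with flanks 1000 bp away for 20 motifs. The DREF site TATCGATA, bound by a factor of housekeeping promoters, was in 2.25% of the windows of 100 bp on each side of a summit against 0.596% of flanks (3.77-fold, adjusted p = 3.11e-16, exact McNemar test, Benjamini-Hochberg over 20 motifs). The M1BP site GGTCACAC of core promoters was in 1.90% against 0.58% (3.27-fold, adjusted exact p = 7.63e-11). Flanks of summits at starts lie away from those starts, and starts without a summit were not compared. Both excesses therefore cannot be told apart from the position of many summits near starts. Smaller excesses were found for the ETS site (1.65-fold, adjusted exact p = 0.00476), the GAGA factor site (1.52-fold, 2.25e-07), the homeodomain core (1.25-fold, 4.38e-08) and the Forkhead site (1.13-fold, 0.00476). The GC-rich site of Mad and Brk was less frequent at summits (2.70 against 3.64%, 0.741-fold, adjusted exact p = 0.0349), as was the EcR/usp element, found in 2 windows (0.267-fold, adjusted p = 0.0349). Summit windows had a lower GC content than flanks, 37.2 against 42.2%, and 2 of these directions turned against shuffled windows of the same dinucleotide content. There the homeodomain core was less frequent at summits (0.893-fold, adjusted exact p = 0.00563) and the Mad and Brk site more frequent (1.57-fold, adjusted p = 0.000222).

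The Smad palindrome GTCTAGAC was found in 9 of 6633 windows (0.136%, 1.38-fold, adjusted exact p = 0.824) and the Schnurri-Mad-Med silencer element in 6 (1.71-fold, adjusted p = 0.887), and neither passed. Nor did the sites of Zelda, CTCF, Su(H), AP-1, Scalloped, Grainyhead, GATA factors and Pho, the CA repeat or the E-box, whose folds ran from 0.763 for Zelda to 1.21 for Pho. DREF, M1BP, ETS, GAGA, homeodomain and Forkhead sites passed at peaks within 1 kb of a start and none of the 6 did at distal peaks, where DREF was at 0.957-fold and M1BP at 1.36-fold. The difference between both kinds of peak was not tested. In the 4729 windows that overlapped no exon, DREF (1.22-fold, adjusted exact p = 0.443), M1BP (1.02-fold, 1), ETS (1.05-fold, 0.695) and the Forkhead site (0.246) did not pass. At distal peaks the E-box (0.690-fold, adjusted exact p = 0.00196) and the CA repeat (0.734-fold, 0.0447) were less frequent than in flanks. Both were also less frequent in windows of 50 bp on each side (adjusted exact p = 0.0113 and 0.00344), as was the E-box among the 3317 strongest peaks (0.00118) and in windows without exons (0.00682), and the Zelda site was less frequent at peaks near starts (0.619-fold, 0.0073). The E-box (2.34-fold), the CA repeat (6.30-fold), CTCF (3.29-fold), Grainyhead (3-fold) and the Smad palindrome (9-fold) were more frequent than in shuffled windows, with adjusted exact p of 0.0358 or less. Flanks were not compared with shuffled windows, so this excess does not set summits apart from other sequence. Over all peaks none of these motifs passed against flanks. There the CA repeat was at 0.909-fold, and the Smad palindrome, in 9 windows, at 1.38-fold. The EcR/usp call ended in all 8 alternatives in which a fold above 0 was counted. Among them were those without replicate 3 (adjusted exact p = 0.227), without replicate 5 (0.444-fold, 0.764), without replicate 6 (0.833) and in windows of 50 bp (0.112). Among the 3317 strongest peaks and those found in all 3 replicates no summit window held the element, and the call stood (adjusted exact p = 0.0246 and 0.0446). Over all peaks it rested on 2 summit windows against 12 in the flank drawn at random. The ETS call ended without replicate 5 (1.43-fold, adjusted exact p = 0.19) and without replicate 6 (1.43-fold, 0.183), and the GAGA call without replicate 5 (1.26-fold, 0.0904) and in windows of 50 bp (1.21-fold, 0.183). The Forkhead call ended without replicate 5 (adjusted exact p = 0.05004) at 1.17-fold, above the fold over all peaks, and in windows of 50 bp (1.10-fold, 0.183). That of the Mad and Brk site ended without replicate 3 (adjusted exact p = 0.0649), among peaks found in all 3 replicates (0.0778), in windows of 50 bp (0.260), in windows without exons (0.277), at peaks near starts (0.348) and at distal peaks (0.188), with folds of 0.682 to 0.788 that lay about the 0.741 of all peaks.

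**Figure D4:**
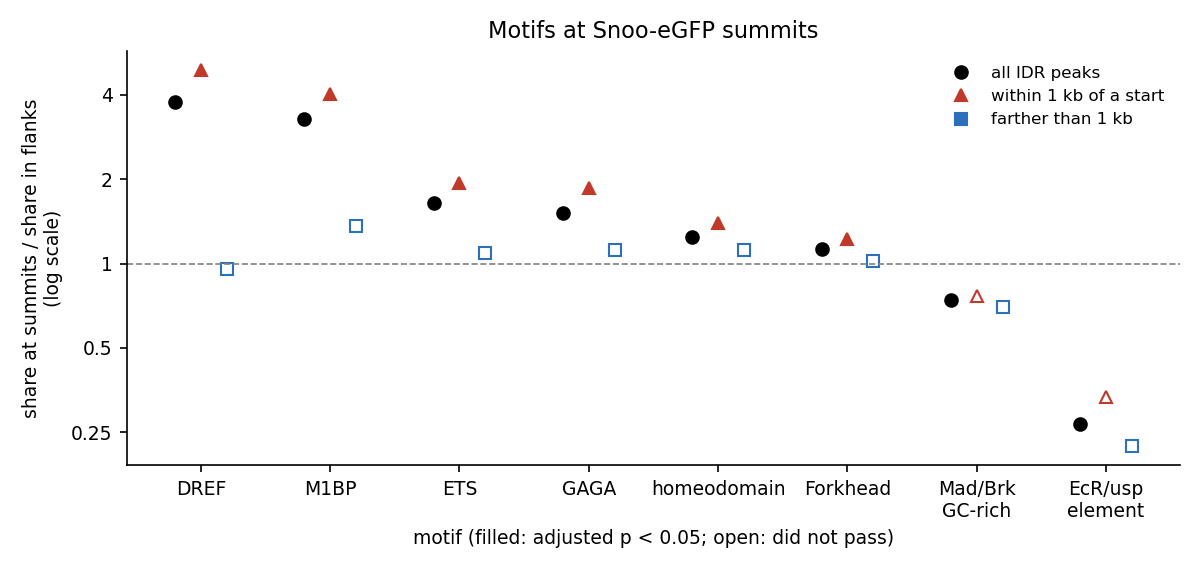
Motifs at IDR summits relative to flanks. The y axis gives the share of windows with the motif at summits divided by that in flanks on a log scale, for all IDR peaks, those within 1 kb of a start and those farther away, with filled symbols for an adjusted p under 0.05. DREF lies at 3.77 over all peaks and at 0.957 at distal peaks.

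The 3 replicates were compared through their strongest 6633 regions each, of which 5 in replicate 3 lay off the main arms. Replicates 5 and 6 shared 70.6% of summits within 150 bp, replicates 3 and 5 67.2% and replicates 3 and 6 65.6%, against 1.46 to 1.47% for shifted lists (permutation test, one-sided, p = 0.001 for each pair, the smallest that 1000 shifts can give). Background shared between the libraries would also exceed shifted lists, so this test does not separate it from binding of the fusion. Of the IDR peaks, 76.1% were found in replicate 3, 79.8% in replicate 5 and 83.0% in replicate 6, a mean of 79.6% ± 3.47 (SD, n = 3). All 3 replicates held 3681 of the 6633 IDR peaks (55.5%), 1917 were in 2 of them, 967 in 1 and 68 in none. With the list divided by signal into 4 equal parts, 97.8% of the strongest part were in all 3, and 82.5, 36.9 and 4.76% of the following parts. The IDR list holds the strongest 6633 regions of the same 3 libraries pooled. Its recovery in each replicate is therefore partly built in, above all for the strongest part, and is not independent support. The ranks of 6097 peaks correlated across peaks, which are not independent replicates, with a Spearman coefficient of 0.709 for replicates 5 and 6, 0.630 for 3 and 5 and 0.586 for 3 and 6.

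**Figure D5:**
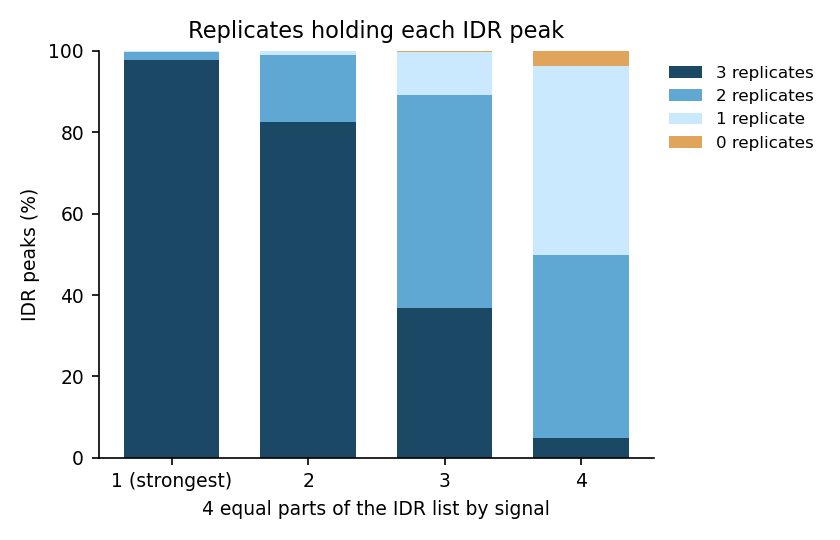
Support of IDR peaks in the replicates. Bars give the share in percent of each of 4 equal parts of the IDR list, ordered by signal, that was found in 3, 2, 1 or 0 replicates among their strongest 6633 regions. Peaks in all 3 replicates make up 97.8% of the strongest part and 4.76% of the weakest. The IDR list was itself drawn from the 3 libraries pooled, so this support is partly built in.

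The authors gave the same libraries on the older dm3 build, where the IDR list held 6501 peaks against 6633 on dm6. Of these, 6495 lay on the main arms, with 1148 on the X and 24 on chromosome 4, against 1174 and 24 on dm6. Candidate regions outside the main arms numbered 30, 40 and 69 for replicates 3, 5 and 6 on dm3 and 6, 0 and 0 on dm6. No coordinates were converted between the builds and no test was made.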

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

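The single result in this part was found after the candidate lists had been read, and no test of it was planned or run. Replicate 3 held 6 candidate regions on the mitochondrial genome, which no comparison above used, while replicates 5 and 6 held 0 each. They lay at 1652 to 2040 (signal 652, rank 9 of the candidates), 3495 to 3654 (signal 398, rank 48), 2525 to 2940 (signal 231, rank 238), 4735 to 4852 (signal 225, rank 255), 1939 to 2046 (signal 54.7, rank 4119) and 2730 to 3145 (signal 20.4, rank 13945). What drew attention was signal outside the arms above a count of 0. On the dm3 build the list of replicate 3 held 1 such region and those of replicates 5 and 6 held 0. None of the 6 is in the IDR list, and no explanation was tested.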

How the results depend on the processing

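The alternative with 1 summit per group of overlapping intervals was chosen after seeing the data, and all others were planned. Of 198 alternative values for gene lists, 168 kept direction and side of the threshold, 19 lost the call, 7 gained one and 4 turned. For motifs these numbers were 151, 29, 10 and 27 of 217 (4 of the 151 stood at exactly 1, with no direction), and for the other results 109 of 140 were kept. Read depth is unknown and limits what can be said of weak peaks. No paired analysis was possible because the series holds 1 group. Where a value changed below, the cause was not tested, except that smaller sets hold fewer bound genes by construction.

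The number of peaks was 3317 among the strongest, 3681 in all 3 replicates and 4347 to 4683 with a replicate left out. IDR peaks found in replicates 3, 5 and 6 rose to 96.0, 97.48 and 97.8% among all candidates, and with overlapping intervals to 79.8% in replicate 3 and 83.4% in replicate 5. The excess of signal near starts lost its call with a window of 500 bp (4.48) and without replicate 6 (1.47, on the lower scale of a single replicate, where the distal median was 75.4), and introns held 38.4% with a 500 bp class.

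Among the 3317 strongest peaks the share of bound genes was 13.9% on 2R, 3.75% on chromosome 4 and 14.8% on the X, and the direction turned for these 3. In peaks of all 3 replicates chromosome 4 had 6.25% (turned). With a replicate left out the shares were 17.7 to 19.2% on 2R, 19.8 to 21.2% on 3L (past the threshold as higher without replicate 5), 7.50 to 20% on chromosome 4 and 16.2 to 19.9% on the X. The Y held 0% of bound genes among the strongest peaks, in peaks of all 3 replicates and without replicate 3, where its test no longer passed, but no list held a region there and the test says nothing.

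Lists past the threshold numbered 11, 7 in peaks of all 3 replicates and 7 to 10 with a replicate left out. The odds ratio of TGF-beta and BMP components lost its call at 1.22 (strongest peaks), 2.35 (all 3 replicates), 1.91 (matched lists) and 1.78 (no shared members). With gene bodies, a count not matched on gene length, Dpp targets (3.64), Wnt (4.99) and sensory organ genes (2.62) gained a call. Of lists that had not passed, muscle turned to 1.08 in peaks of all 3 replicates, homeodomain factors to 1.71 with gene bodies and 1.01 at 500 bp, and Hedgehog to 0.987 without shared members.

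Motifs past the threshold numbered 8, 2 at distal peaks (E-box and CA repeat, both less frequent), 3 in windows without exons and 4 to 6 with a replicate left out. Folds turned at proximal peaks for the CA repeat (1.07), E-box (1.07), Scalloped (0.795) and Su(H) (1.15), and at distal peaks for DREF (0.957) and Zelda (1.02). Against shuffled windows they turned for AP-1 (1.02), the CA repeat (6.30), E-box (2.34), Mad and Brk (1.57), Scalloped (0.882) and homeodomain (0.893). In peaks of all 3 replicates they turned for Grainyhead (0.48) and Su(H) (1.07), among the strongest peaks for AP-1 (1.08), GATA (0.977), Grainyhead (0.348) and Pho (0.885), and with 50 bp windows for GATA (0.998) and Scalloped (0.976). With a replicate left out the folds were 0.333 to 1.5 for the silencer, 0.943 to 1.09 for AP-1, 0.919 to 1.04 for Scalloped, 0.645 to 1.07 for Grainyhead and 0.851 to 1.07 for the CA repeat.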

Other observations

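The lists, sequences and counts in this part were chosen after the main results were seen. The tests of gene length, starts used in all cells and core promoter sequences also followed values that bear on them. Some members of the added lists were already known to be bound (mRpL41, Hsp27, gro, sbb, psq, InR and Ptp61F), so their lists are not independent of those values.

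Among 16 further gene lists 7 passed against all other genes. Of 19 Polycomb and trithorax group genes 13 were bound (68.4%, odds ratio 6.44, adjusted p = 0.00101, Fisher's exact test over 16 lists), the strongest being ph-p (X 2136798 to 2137614, signal 1903), brm (signal 1515), E(z) (signal 766) and ph-d (signal 604). Of 16 corepressor and histone deacetylase genes 11 were bound (odds ratio 6.53, adjusted exact p = 0.00165), led by sbb (2R 18357215 to 18357699, signal 1210), gro (signal 863), Gug (signal 544) and Sirt1 (signal 449). Insulin and TOR genes were bound in 10 of 16 cases (odds ratio 4.95, adjusted exact p = 0.00472), with Sesn (signal 1792) and Akt (signal 1230) above InR (298) and Thor (263). Genes of respiratory complexes III and IV and ATP synthase were bound in 13 of 25 (odds ratio 3.22, adjusted exact p = 0.00995), with ATPsynE the strongest (signal 505). Odorant-binding proteins (2 of 51 bound, adjusted p = 0.00101), cytochromes P450 (8 of 83, 0.00195) and trypsin-like proteases (0 of 28, exact upper limit 12.3%, 0.00195) were bound less often. Mitochondrial ribosomal proteins (26 of 73), translation factors (19 of 52), the proteasome (11 of 32), complex I (10 of 34), aminoacyl-tRNA synthetases (8 of 35), heat shock proteins (8 of 19), glutathione and UDP transferases (10 of 70), JAK-STAT (3 of 9) and clock genes (4 of 8) did not pass, with adjusted exact p between 0.0753 and 0.847.

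Against random lists matched on gene length and number of starts, Polycomb and trithorax genes (odds ratio 3.83, adjusted permutation p = 0.0288), complexes III and IV with ATP synthase (2.96, 0.032), cytochromes P450 (0.343, 0.0096) and also mitochondrial ribosomal proteins (3.18, 0.0032) passed. Corepressors (3.22, adjusted permutation p = 0.08), insulin and TOR genes (3.19, 0.08), odorant-binding proteins (0.224, 0.0608) and trypsin-like proteases (0.116, 0.113) did not. The call of complexes III and IV ended without replicate 3 (1.92, adjusted exact p = 0.175), without replicate 5 (2.14, 0.177) and without replicate 6 (2.39, 0.0809), and that of insulin and TOR genes without replicate 3 (3.17, 0.0563). The odds ratio was 3.30 for Polycomb and trithorax genes and 0.184 for odorant-binding proteins without replicate 5, and 12.3 for corepressors without replicate 3. Translation factors passed without replicate 5 (2.21, adjusted exact p = 0.0278) and without replicate 6 (2.25, 0.0195).

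Several long genes held many summits, and counting the gene body and 1 kb around it, sbb, Eip75B and Tet held 25 each, CG1677 23, kirre 20, and ush and shn 18 each. Shifted summits gave a mean of 3.95 in sbb (permutation p = 0.002), 2.99 in shn (p = 0.004) and 19.8 in kirre (p = 0.484), each from 1000 shifts and without adjustment for the choice of genes. The highest count of any gene, 25, lay below the mean highest count of shifted summits, 98.8. Genes with 10 or more summits numbered 45, against a mean of 54.8. Among these 45 genes the highest shifted mean was 19.8, in kirre. The shifted highest counts may thus come from genes outside these 45. These comparisons therefore cannot decide whether the counts of the named genes exceed what shifted summits give. Shorter genes stood above their own shifted means, with 16 summits in tara (mean 1.71, permutation p = 0.002) and Mnt (1.62, 0.003), 12 in CHES-1-like (1.41, 0.004) and 11 in CG14434 (0.834, 0.001). Among genes shorter than 40 kb, 7 had 10 or more summits against a mean of 4.94 in shifted lists (permutation p = 0.228), and 28 genes of any length exceeded their own span against a mean of 21.5 (p = 0.0739), so single genes above chance are not excluded. Genes with 10 or more summits included 6 of 27 ecdysone response genes (22.2%), EcR, Eip74EF, Eip75B, Hr3, Hr4 and tai, against 0.28% of other genes. This exceeded random lists drawn from the same 10 classes of gene length (permutation p = 0.0001, the smallest 10000 lists can give, adjusted p = 0.0034 over 34 lists). These classes are coarse for long genes, and against shifted summits at their own span EcR (permutation p = 0.0699), tai (0.0519) and Hr4 (0.0849) did not pass, while Eip75B (0.022), Eip74EF (0.036) and Hr3 (0.021) did, without adjustment, so the share of gene length in this list stays open.

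The binding of ribosomal protein genes exceeded that of random lists matched on gene length and number of starts (odds ratio 21.9, permutation p = 0.0002, the smallest 10000 lists can give). Of the 76 bound genes, 97.4% had their own start nearest to the summit. These values argue against gene length and against neighbouring genes. Of 174 genes of the mitochondrial ribosome, the proteasome, complex I and aminoacyl-tRNA synthetases, 4 groups used in all cells, 31.6% were bound (exact interval up to 39.1%), and respiratory complexes III and IV with ATP synthase (52%, up to 72.2%) and translation factors (36.5%, up to 51.04%), left out of this share, also lay below the lower limit of the ribosomal proteins, 80.8%. Of 290 tRNA genes 14.5% were bound, against 8.34% for shifted summits (p = 0.034, permutation test), and together these values argue against a signal at every start used in all cells, or at loci transcribed by any polymerase, as the whole cause. What stays open is a signal that any precipitation would give at the most transcribed protein-coding genes alone, since transcription was not measured and the control alignment was not analysed here. Repeated tRNA genes limit mapping, and no biological explanation was tested.

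Replicate 3 held fewer regions on the X than the others. The X had 4633 of its 30000 candidates against 5488 and 5319 in replicates 5 and 6, and 14.6% of its strongest 6628 regions on the arms against 18.4% in the others (p = 2.22e-11, Fisher's exact test over regions), so the gap was not limited to weak candidates. Peaks on the X ranked lower in replicate 3 by 473 places more than autosomal peaks (bootstrap interval 334 to 639, permutation p = 0.0002, the smallest 10000 resamples can give), which restates the lower share and does not bear separately on its cause. A lower dose of the X in that pool and a different background on the X cannot be told apart here, because the labels give the sex only as pooled. Replicate 3 was also lowest on chromosome 4, with 189 candidates against 277 and 523 in replicates 5 and 6, which was not tested. Peaks are not independent replicates.

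Short sequences shared by summits were sought on 2L, 2R and X and tested on 3L and 3R. All 10 sequences of 6 bases found were more frequent on the held-out arms (1.51- to 2.31-fold), 8 of them made of A and T and the others being ACACTG (17.3 against 7.51% of windows, adjusted exact McNemar p = 4.63e-32) and ACAGTG (15.6 against 7.64%, adjusted p = 1.9e-21). The lower GC content of summits (37.2 against 42.2% in flanks) could alone raise sequences of A and T, and 5 sequences rich in G and C that were less frequent on the discovery arms were less frequent on the held-out arms too (0.291- to 0.482-fold). In a search for 8 bases, CACTGAGA was in 3.98% of held-out windows against 0.526% of flanks (7.56-fold, adjusted exact p = 2.15e-19), CTCAGTGC in 2.70 against 0.444% and TCAGTGCA in 3.68 against 0.789%.

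For the sequences with G and C, either of ACACTG and ACAGTG was in 30% of distal windows against 13.1% of flanks (2.29-fold, exact McNemar p = 5.9e-30) and in 27.0% of proximal windows against 13.5%, which argues against a core promoter sequence. With 10 bases on each side, 2562 occurrences were all distinct (100%), which excludes identical copies of a repeat and not diverged ones. A protein that recognises such a sequence may sit at these summits, and open chromatin with the same sequence remains an alternative. No biological explanation was tested.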
